A study of Mus musculus with 2 samples.

How the data were processed

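DNase-seq was analysed from 4 deposited peak lists, 2 for estradiol-treated G1E-ER4 cells and 2 for untreated G1E cells, grouped by the cell named in the labels. Per the series design text, nuclei were digested with DNase I at several enzyme concentrations, the cleaved ends were captured by an adaptor whose enzyme leaves very short tags, and these were sequenced on an Illumina instrument. The same text says that tags were aligned to mm9 with Bowtie, that tags with several matches were kept at their best place, that lanes were pooled per replicate, that SAMtools was used for conversion, that F-seq turned the tags into a smoothed density, and that peaks were taken from this density by a gamma fit. Tool versions, the number of reads and the threshold are not given in the sources used here. Keeping such tags can place peaks in repeats and in any sequence that is over-represented in the library. Peaks were called per list and not on pooled lists, per the series design text.

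The value of each peak is a signal, the F-seq density that the authors deposited, and no scaling between lists is stated. It was therefore used only to rank and filter peaks within a list, as a percentile (100 for the highest). In the deposited lists the score column was 0 and the p and q columns were -1 for every peak, so they were not used. Every list held 100000 peaks sorted by signal. Median peak widths were 579 and 836 bp in G1E-ER4 lists 1 and 2 and 520 and 646 bp in G1E lists 1 and 2, the lists covered 90.7, 112.6, 76.5 and 99.6 Mb, and mean GC was 49.7, 55.1, 54.0 and 52.0%. The share of promoters among the strongest 10% of peaks was 55.1, 79.0, 72.8 and 71.2% in the same order, so G1E-ER4 list 1 stands apart from the rest. Chromosome Y had 12, 0, 3 and 6 peaks. Read depth is unknown, and intervals cover the counting of regions only.

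Peaks of the 4 lists that overlapped by at least 1 bp were merged, and each region was classed by the lists it held. Regions of all 4 lists had a median width of 2203 bp, G1E-ER4-only regions 1036 bp and G1E-only regions 715 bp, so merging can hide changes inside wide regions. A region counts as one-state when both lists of a state and no list of the other have a peak. Strong regions have their best peak in the top 25% of both lists. The same counts for the 2 crossed divisions of the lists serve as the noise level. Regions were placed with the GENCODE vM1 protein-coding annotation on mm9 as promoter (within 1000 bp of a start), exon, intron or between genes. They were given to the gene with the nearest start, within 50000 bp for gene lists and counts per gene. Coordinates are 1-based on mm9.

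Chromosome, promoter and motif shares were compared with Fisher's exact test, two-sided, and Wilson 95% intervals. The excess of one-state regions at 14 gene lists was set against 10000 random lists matched on the number of regions per gene. The 14 lists are globin, heme and iron, red cell membrane, erythroid transcription factors, erythroid survival and maturation, progenitor, megakaryocyte, granulocyte, monocyte and mast cell, lymphoid, pluripotency, liver and neural, estrogen receptor target, cell cycle and housekeeping genes. Some genes stand in more than 1 list, Myb among them. Motifs were 15 fixed patterns, 2 of them shuffled GATA controls, searched on both strands in 200 bp around the summit. Clustering counted 100 kb windows with 4 or more regions of a class against 100 shuffles. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05.

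Lists, motifs, main tests and alternatives were fixed before the data were examined, as was the rule for named genes, apart from the alternatives that the text names as chosen after seeing the data and the crossed values for chromosomes, genes, clustering and strong motifs, which were also added later. It names in each list the 4 genes with most one-state regions, the 10 genes with most regions of each class over the genome, the study's factor Gata1 with 10 known targets, the 10 regions of each class with the highest mean percentile, and the 5 densest windows per class. For brevity the text gives those genes of each list that carry its count. Of the 10 genes with most G1E-ER4-only regions, 1 is not reported here. The other genes named in the account of promoters and in the closing observations were chosen after their values were seen. Several other rank limits were looked at in exploration, and the rank limits reported are those set in advance. Alternatives were overlap of 50% of both peaks, summits within 100 bp, the top 50% or top 20000 peaks, an asymmetric threshold, merging across 150 bp, autosomes and X alone, other windows, promoter and gene distances, GC matching, regions outside promoters, and leaving out each list. The steps were tested on simulated data. Among 9000 simulated regions, the classes checked were recovered in their simulated number (100%), though not every pattern of lists was checked. Of 1000 unchanged gene lists, 4.3% had p under 0.05. A motif planted in 30% of regions, some of which held it by chance, gave a difference of 20.1 points. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1.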

Results

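DNase I hypersensitive sites, stretches of chromatin open enough for the nuclease DNase I to reach the DNA, were mapped in 2 states of a mouse erythroid cell system. G1E cells are immature erythroid progenitors without Gata1, the transcription factor that drives red cell maturation. In G1E-ER4 cells Gata1 is restored in a form that estradiol switches on, and the cells were collected after 24 h with 10 nM beta-estradiol. G1E cells received no treatment, so the comparison sets cells resuming maturation under Gata1 against cells held before it. Cell line, restored gene, estradiol and sample differ together, as no untreated G1E-ER4 and no treated G1E sample is present. Their effects cannot be told apart. Each state was 1 sample with 2 peak lists, and every list held 100000 peaks on the mm9 assembly. The labels do not say whether the 2 lists of a state came from separate cultures, so the spread between them may be technical. The read depth of the lists is unknown. Equal list lengths mean that a peak gained in a list displaces another, and a percentile (100 for the strongest peak) gives only a peak's place within its own list. The 4 lists can be divided into pairs in 3 ways, so no p-value between the states can lie under 0.333, the smallest share that 3 splits allow. The 2 divisions that pair a G1E-ER4 list with a G1E list, called crossed, give the noise level. Fisher's exact tests over regions, all two-sided, compare these lists and not the cell states.

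At Gata1 itself, both G1E-ER4 lists held 2 strong peak regions over the last exons of the gene that neither G1E list held. They spanned X:7536714-7538015, at percentiles 89.5 and 89.2 in G1E-ER4 lists 1 and 2, and X:7538924-7540486, at percentiles 89.2 and 88.7. All 6 G1E-ER4 peaks inside them had their summits in exons. The 5 exons of this stretch (X:7536386-7540367) had no G1E peak. Upstream in the gene, 1 region in an intron (X:7548156-7549347) lay at percentiles 82.7 and 91.4 in G1E-ER4 and 86.7 and 90.3 in G1E, and a promoter region at X:7544602-7546126 was also in all 4 lists. Peak lists record open chromatin, so they do not test the loss of Gata1 in G1E cells. The restored gene is an added copy, and reads of an added copy map to the same exons.

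**Figure D1:**
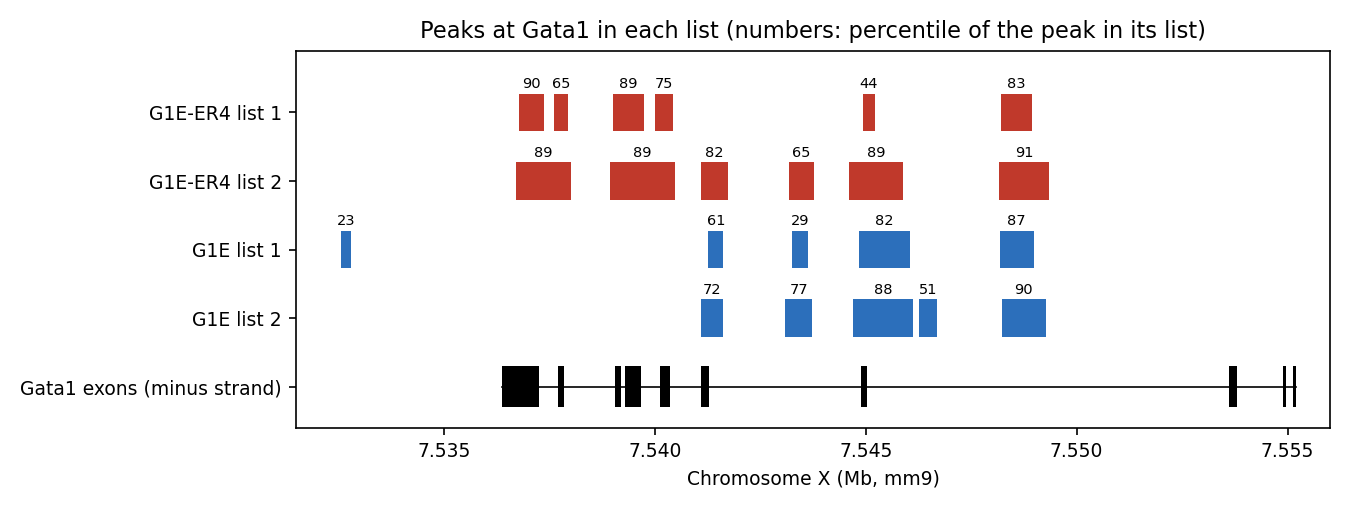
Peaks of the 4 lists along Gata1 on chromosome X (position in Mb, mm9), with the annotated exons at the bottom and each peak's percentile within its list above it. Peaks of both G1E-ER4 lists, at percentiles up to 89.5, cover the 5 exons at the left end, where neither G1E list has a peak.

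Most genes of the erythroid program had an open promoter in both states. A listed gene's promoter counted for a list if any peak of that list reached within 1000 bp of any annotated start. The lists can therefore meet different starts of a gene. All 19 erythroid transcription factor genes had a promoter peak in all 4 lists, among them Klf1, which activates adult globin genes, Zfpm1, the cofactor FOG-1 that binds Gata1, and Tal1, which binds DNA in complexes with Gata1. The same held for 20 of 21 heme and iron genes (95.2%, Wilson 95% interval 77.3 to 99.2%), 22 of 23 erythroid survival and maturation genes (95.7%), 19 of 24 red cell membrane genes (79.2%) and 22 of 27 progenitor genes (81.5%). All 24 cell cycle and all 19 housekeeping promoters were in all 4 lists. The globin genes were an exception, with 2 of 7 (28.6%). The shares of other lineages, not tested against these, were 10 of 22 megakaryocyte genes (45.5%), 8 of 22 lymphoid genes (36.4%), 7 of 25 granulocyte, monocyte and mast cell genes (28.0%), 9 of 16 estrogen receptor targets (56.2%), 5 of 17 pluripotency genes (29.4%) and 9 of 19 liver and neural genes (47.4%). Some of their intervals overlap those of the erythroid lists, as for red cell membrane genes (59.5 to 90.8%) and estrogen receptor targets (33.2 to 76.9%).

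**Figure D2:**
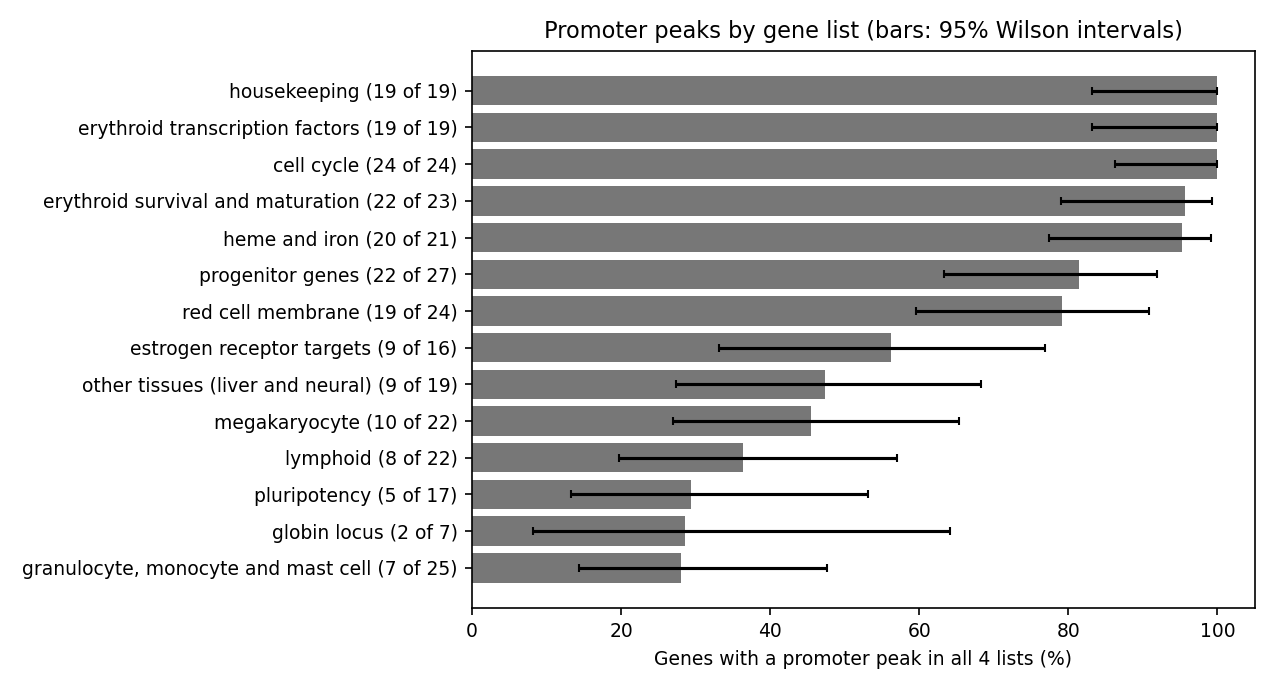
Share of each fixed gene list (%, horizontal axis) whose promoter holds a peak in all 4 lists, with Wilson 95% intervals. The shares run from 28.0% for granulocyte, monocyte and mast cell genes to 100% for erythroid transcription factor, cell cycle and housekeeping genes.

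Of 10 Gata1 target genes chosen in advance, 8 had a promoter peak in all 4 lists, all but Hbb-b1 and Alas2. One-state regions were absent from 8, all but Kit and Hba-a1. Over the genome only 2.35% of merged regions were G1E-ER4-only and 3.99% G1E-only, and Klf1 and Zfpm1 had 1 assigned region each. The number of targets without a one-state region was not set against other genes. Klf1 (8:87424147-87427824) and Slc4a1, the band 3 anion exchanger of the red cell membrane (11:102224041-102227665), had promoter regions at percentiles from 90.6 to 96.1 in the 4 lists. Gata2, which Gata1 is known to silence during maturation, lay in a single wide region (6:88137843-88158868) at percentiles 97.0 and 98.4 in G1E-ER4 and 97.3 and 98.0 in G1E. These are the percentiles of the best peak in the region, so they cannot show whether single sites inside it changed. Another 14 regions assigned to Gata2 were neither one-state nor in all 4 lists. Myc, which promotes growth and also falls during maturation, had its promoter region (15:61814366-61821709) between percentiles 92.9 and 96.0. The beta-globin gene Hbb-b1 differed in level, with a promoter region (7:110975618-110976859) at percentiles 92.9 and 90.9 in G1E-ER4, 61.7 in G1E list 2 and no peak in G1E list 1. The alpha-globin gene Hba-a1 (11:32182279-32188028) stood at percentiles 92.8 and 94.3 in G1E-ER4 and 99.8 and 95.9 in G1E. Only 2 of 7 globin genes had a promoter peak in all 4 lists. Near-identical globin copies share short reads, so their values are uncertain. Alas2, the first enzyme of heme synthesis in red cells, had a promoter peak in G1E-ER4 list 2 alone, and 2 of its intron regions were in all 4 lists.

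Few listed promoters were open in 1 state only. Both G1E-ER4 lists and no G1E list marked the promoters of the lymphoid genes Cd2, Cd79b and Rag1 and the estrogen receptor targets Wisp2 and Esr1, the last at different annotated starts in the 2 lists. The mast cell tryptase gene Tpsab1 was the only listed gene with a promoter peak in both G1E lists and no G1E-ER4 list. The Cd79b region (11:106174573-106176369) had percentiles 47.1 and 50.9. Crossed pairs marked listed promoters in the same way. G1E-ER4 list 2 and G1E list 1, and no other list, marked Cxcl12, F2rl2, Klf4, Pgr and Sox4. G1E-ER4 list 2 and G1E list 2 alone marked Cebpe, Hbb-b2, Rab27b and Rhag. The 6 promoters of 1 state are therefore not beyond the spread between lists.

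Over the genome, the G1E lists held more regions of their own than the G1E-ER4 lists did. Merging the lists gave 187971 regions, of which 29567 (15.7%) were in all 4 lists, 4414 only in both G1E-ER4 lists and 7505 only in both G1E lists. The G1E-only count lay above the crossed pairs, which gave 3131, 5341, 4307 and 6125 regions. The G1E-ER4-only count lay inside that range. In both crossed divisions too, the side with G1E-ER4 list 1 had fewer regions (3131 against 5341 and 4307 against 6125), so the imbalance between the sides is not beyond the effect of that list. Another 109920 regions (58.5%) were in a single list. Within G1E the lists shared 59.4% of their peaks (Jaccard index 0.428) and within G1E-ER4 49.2% (0.295), while the 4 pairs across states shared 49.6 to 56.2%. The mean within states (54.3%) thus exceeded the mean between states (52.6%) by 1.75 points, less than the SD over the 6 pairs, 4.14 points. The excess was 0.229 points with 50% reciprocal overlap, 3.20 in the top 50% and 2.83 in the top 20000. Among the top 20000 peaks of each list, 1019 G1E-ER4-only and 1232 G1E-only regions were found against 527 to 767 for the crossed pairs. Of the other ways to set overlap or rank, the G1E-ER4 count passed the noise level in this one alone. It lay below it with 50% reciprocal overlap (5061 against 6019 to 8817) and with summits within 100 bp (3758 against 4026 to 7833). It lay inside it (744 against 488 to 1351) when top 50% peaks of both lists met no peak at all of the other state. With 50% reciprocal overlap or summits within 100 bp, peaks of list 1 of a state were counted rather than merged regions. A peak there counted as restricted when no peak of the other state met the rule, even if 1 overlapped it.

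**Figure D3:**
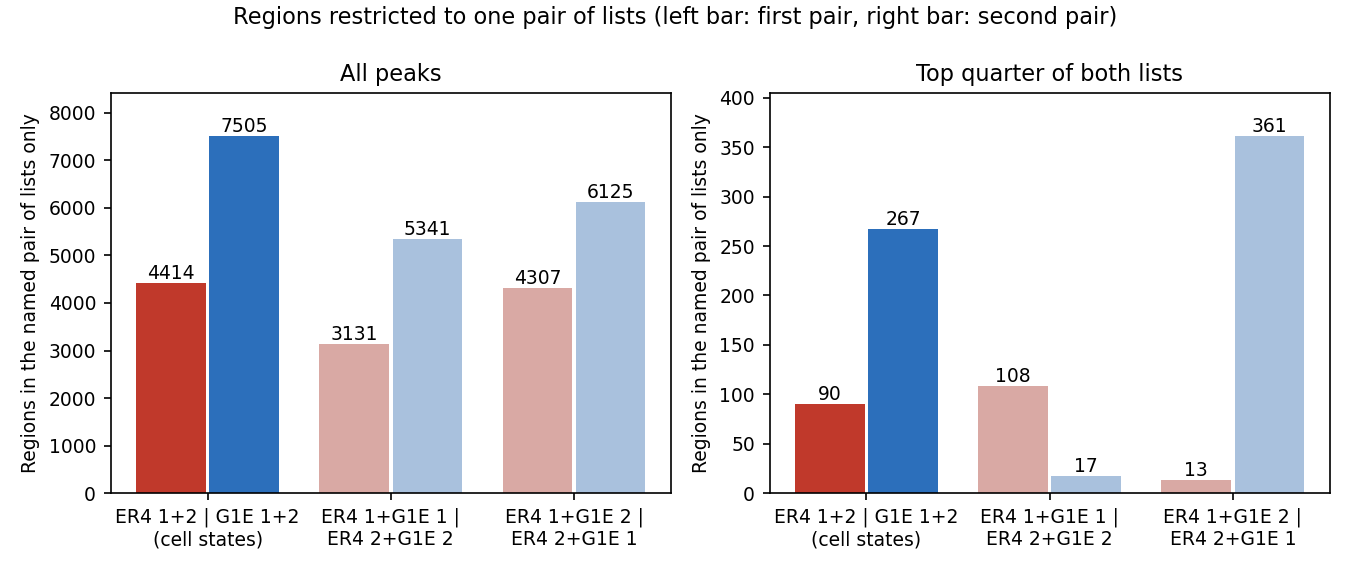
Number of regions restricted to a pair of lists (vertical axis), for the division by cell state (dark bars) and the 2 crossed divisions (light bars), over all peaks (left) and for peaks in the top 25% of both lists (right). Over all peaks the G1E pair, with 7505 regions, is above every crossed pair, and the G1E-ER4 pair, with 4414, is not.

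Strong regions, in the top 25% of both lists of a state, included regions at Myb in G1E and at Gata1 in G1E-ER4 beside many other genes. Of 267 strong G1E-only regions, 1 lay in an intron of Myb (10:20870585-20871607), which keeps progenitors dividing, at percentiles 84.8 and 85.5. The 10 strongest included 3 at Arhgef10l, of which 4:140142231-140143567 in an intron reached percentiles 93.1 and 94.6 and 4:140136990-140142204 at a promoter 90.7 and 96.1. A promoter region of Mccc2, a leucine breakdown enzyme gene (13:100785125-100785956), stood at 89.9 and 93.4. The rest of these 10 lay at or near Cacng1, Kif20b, Rab8a, Nmnat2, Gpn1 and Tbx21. Among 90 strong G1E-ER4-only regions, the strongest lay between genes 19246 bp from a start of Cdc42ep2 (19:5937234-5938871, percentiles 94.3 and 88.7), followed by an intron of Gpr124 (8:28198287-28201000, 90.3 and 90.9). The same 10 held the 2 Gata1 regions, 2 regions nearest to E2f8, a repressor of the cell cycle (7:56245807-56248931 and 7:56183420-56184631), and regions at or near Trak1, Gm11016, Wfikkn2 and Sdk2. The crossed pairs gave 108, 17, 13 and 361 strong regions, so neither strong count stood outside the noise level. Some regions of the 108 and 361 held bases of a sequencing primer or of repeats near the summit. Without all regions that did, an alternative chosen after seeing the data, 85 G1E-ER4-only and 263 G1E-only strong regions remained against 90, 17, 13 and 236. The G1E count then lay above the noise level and the G1E-ER4 count did not. In the top 10% the counts were 1 and 3.

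Genes with many regions of 1 state were found in both directions. At least 7 G1E-ER4-only regions lay at 12 genes and at least 7 G1E-only regions at 28, against 0 to 6 genes for the crossed pairs, whose single highest gene had 13. Arhgef10l had 15 G1E-only regions and 1 G1E-ER4-only region, and Erg, an ETS factor of blood stem cells and megakaryocytes, had 14 and 0. One Erg region lay at a promoter (16:95806822-95808120, percentiles 58.2 and 66.2) and the others in introns. Tns4, a focal adhesion gene, had 13 G1E-only regions, Ptpre, a tyrosine phosphatase gene, 10 and Rbms1, which encodes an RNA-binding protein, 9. The other 5 of the 10 genes with most G1E-only regions, Wdr25 (13), Sipa1l1 (11), Ppp1r13b, Ppp2r5c and A730018C14Rik (10 each), were all on chromosome 12. In the other direction Nav2, a neuron navigator gene, had 14 G1E-ER4-only regions and no G1E-only region. Sulf2, a heparan sulfate sulfatase gene, had 12, the integrin gene Itga9 11, the cadherin gene Cdh22 and the CREB coactivator gene Crtc3 9 each, and E2f8, Actn4, Mesp2 and Ezr 7 each. Ezr lay in a 10 Mb window with a log2 ratio of G1E-ER4 to G1E peaks of 0.04, and the other genes named here lay in windows from 0.46 to 1.03. The windows of Erg (-0.10), Arhgef10l (-0.16), Tns4 (-0.05) and Ptpre (0.04) were nearly balanced, while that of Rbms1 (-0.56) was lower in G1E-ER4.

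Genes of the progenitor list had the largest difference in number of the 14 lists fixed in advance, with 5 G1E-ER4-only and 37 G1E-only regions. Beside Erg, Kit, the stem cell factor receptor that is lost in maturation, had 0 and 4, Runx1, which specifies blood stem cells, 2 and 4, and Fli1, an ETS factor of megakaryocytes, 2 and 2. The strongest Kit region lay between genes (5:75949995-75951022, percentiles 59.4 and 61.9). The difference had an excess of -26.4 regions over the mean of 10000 random gene lists matched on regions per gene (p = 0.0123, adjusted p = 0.172, permutation of gene lists, Benjamini-Hochberg over 14 lists). None of the 14 lists passed, and 1 had an unadjusted p under 0.05. With random lists also matched on chromosome, an alternative chosen after seeing the data, the progenitor list passed (permutation, adjusted p = 0.0294), as it did without G1E list 1 (10 and 148 regions, adjusted p = 0.0182), while over all alternatives the adjusted p ran from 0.0182 to 0.762. Without G1E-ER4 list 2 the progenitor list did not pass and 3 others did, the red cell membrane, erythroid transcription factor, and liver and neural lists. A crossed split called 2 lists in the same permutation test, erythroid survival and maturation (adjusted p = 0.0056) and megakaryocyte (0.0119), so the lists reach such values without a difference in state.

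The other lists held fewer G1E-only regions, and none passed the test. In proportion, the housekeeping and the granulocyte, monocyte and mast cell lists were more one-sided than the progenitor list. The red cell membrane list had 6 G1E-ER4-only and 22 G1E-only regions, 8 of the latter at the spectrin gene Spnb1 on chromosome 12. Erythroid transcription factors had 6 and 16, with 0 and 3 each at Myb, the lymphoid and erythroid regulator Ikzf1, and the cell cycle activator E2f2. A further Myb region lay in an intron at 10:20850542-20851714 (percentiles 67.0 and 73.7 in G1E). Heme and iron genes had 8 and 9, with 0 and 4 at the ferritin heavy chain gene Fth1. Erythroid survival and maturation genes had 4 and 2, where the antiproliferative gene Btg2 had 2 and 0. Granulocyte, monocyte and mast cell genes had 1 and 10, including 0 and 2 each at Csf2ra and the chymase gene Cma1. Pluripotency genes had 4 and 11, of which Esrrb on chromosome 12 held 8 of the latter, and estrogen receptor targets 2 and 10. Megakaryocyte genes had 2 and 2, lymphoid genes 3 and 4, liver and neural genes 7 and 5, cell cycle genes 3 and 4, housekeeping genes 0 and 8 and globin genes 0 and 1.

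The 2 states differed by chromosome. Chromosome 7 held 17.3% of G1E-ER4-only regions (Wilson 95% interval 16.2 to 18.5%) and 3.52% of G1E-only regions (3.12 to 3.96%), an odds ratio of 5.75 (adjusted p = 2.6e-142, Fisher's exact test). Chromosome 12 held 1.34% and 14.6%, an odds ratio of 0.0790 (adjusted p = 4.1e-157, Fisher's exact test). Chromosome 3 (6.66% and 2.47%) and chromosome 9 (7.84% and 4.40%) leaned to G1E-ER4, with odds ratios of 2.82 and 1.85, and chromosome X held 0.272% and 1.16%. The crossed pairs held 5.69 to 6.23% of their regions on chromosome 7, 4.03 to 5.14% on chromosome 12, 3.69 to 5.20% on chromosome 3 and 5.11 to 5.49% on chromosome 9, so both states lay outside the noise level on each of these. In all, 12 of 20 chromosomes had an adjusted p under 0.05 (Benjamini-Hochberg over chromosomes). The lists themselves moved together, as chromosome 7 held 9.07% and 9.01% of all peaks in the G1E-ER4 lists and 6.63% and 6.32% in the G1E lists, and chromosome 12 held 3.78%, 3.87%, 6.81% and 7.07% in the same order. In the top 50% of each list the odds ratio of chromosome 9 fell to 1.07 (adjusted p = 0.662, Fisher's exact test) and that of chromosome 12 was 0.127. With 50% reciprocal overlap the odds ratios of chromosomes 7, 12 and 3 were 2.24, 0.370 and 1.88.

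On chromosomes 7, 9 and 12 the imbalance began or ended within the chromosome. On chromosome 12, the log2 ratio of G1E-ER4 to G1E peaks was 0.17 to 0.32 in the 10 Mb windows up to 30 Mb, -0.44 from 30 to 40 Mb, and between -1.16 and -0.84 in windows from there to 120 Mb. On chromosome 7 it was 0.35 to 1.19 up to 100 Mb and -0.11 to 0.16 beyond. The end of chromosome 9, which holds Itga9, had ratios of 1.03 from 110 to 120 Mb and 0.86 in the last window, against -0.23 to 0.18 before. The window of chromosome 2 from 160 to 170 Mb, with Sulf2 and Cdh22, stood at 0.48. Chromosome 3 was raised over most of its length, from 0.48 in its first window to 1.02 in its last, with 2 windows near balance (0.03 and -0.02). Without chromosomes 3, 7, 9 and 12, an alternative chosen after seeing the data, 2950 G1E-ER4-only and 5627 G1E-only regions remained beside 2506 to 4920 for the crossed pairs.

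Regions of 1 state lay away from promoters, as did regions of the crossed pairs. Promoters, within 1000 bp of a transcription start, made up 34.8% of the regions in all 4 lists (Wilson 95% interval 34.3 to 35.4%), 7.91% of G1E-ER4-only regions (7.15 to 8.74%) and 5.41% of G1E-only regions (4.92 to 5.94%). Introns held 50.7% of G1E-ER4-only and 45.9% of G1E-only regions against 29.6% of those in all 4 lists. Exons outside promoters held 7.34%, 4.21% and 4.64%, and the rest lay between genes. The promoter shares of the states differed by 2.50 points (p = 1.1e-07, Fisher's exact test), by 7.526 points in the top 50% of the lists and by 11.6 points with promoters taken to 5000 bp. The crossed pairs gave promoter shares from 4.34 to 17.3%, a range that contains the shares of both states. The low shares are therefore not particular to regions of 1 state, and the difference between the states is within the noise level between lists.

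Some binding motifs differed in share between the 2 one-state classes of regions, most of all the motif of PU.1, an ETS factor of progenitor and myeloid cells that opposes Gata1. Within 100 bp of the summit it was present in 7.42% of G1E-only regions (Wilson 95% interval 6.85 to 8.04%) and 1.56% of G1E-ER4-only regions (1.24 to 1.97%; adjusted p = 6.2e-50, Fisher's exact test, Benjamini-Hochberg over 15 motifs). The crossed pairs ranged from 1.15 to 3.97%, so the G1E share lay above them. Crossed pairs with G1E list 2 (3.97 and 2.88%) had higher shares than those with G1E list 1 (1.15 and 1.70%). The G1E-only share was 6.16% without G1E list 1 but 3.18% without G1E list 2, a value inside the crossed range. Much of the excess thus went with G1E list 2. The difference of -5.86 points shrank to -1.39 without G1E list 2. By the same exact test, the RUNX motif (16.1% in G1E-ER4-only and 20.4% in G1E-only regions, adjusted p = 3.1e-08) and the MYB motif (38.0% and 42.2%, adjusted p = 2.6e-05) were also more frequent in G1E-only regions, whose shares again lay above the crossed ranges of 14.6 to 18.4% and 34.3 to 39.2%. CTCF, which marks chromatin boundaries, was rare in both (1.20% and 2.17%, adjusted p = 0.00033, Fisher's exact test) and at 9.47% in regions of all 4 lists. The crossed pairs (0.511 to 3.32%) contain both CTCF shares, so this difference is within the noise level. Over whole regions, which are wider in G1E-ER4, the RUNX and MYB differences had the opposite sign (10.8 and 7.82 points). Without G1E list 2 so did those of MYB (1.76 points) and CTCF (2.06 points), while that of RUNX did not pass (-0.65 points, adjusted p = 0.294, Fisher's exact test). The MYB difference was -1.55 points without G1E-ER4 list 2. That of CTCF did not pass in the top 50% and was -2.20 and -3.13 points without G1E-ER4 lists 1 and 2, and -0.567 points without G1E list 1.

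The GATA motif was frequent in both one-state classes. It lay near the summit of 38.8% of G1E-ER4-only regions (Wilson 95% interval 37.4 to 40.2%) and 35.7% of G1E-only regions (34.6 to 36.7%; adjusted p = 0.0020, Fisher's exact test), both above the crossed pairs (21.8 to 32.2%) and the regions in all 4 lists (28.2%). GATA with an upstream E-box, the composite site of Gata1 with Tal1, was at 11.4% and 9.85% (adjusted p = 0.0174, Fisher's exact test; crossed pairs 5.50 to 7.86%). Shuffled control 2 was at 19.1% and 20.0%, inside the crossed pairs (14.3 to 24.8%) and above the regions in all 4 lists (14.7%), so the excess over those regions was not particular to GATA. Mean GC near the summit was 51.3%, 49.9% and 56.9% in the same classes. Shuffled control 1 can overlap a GATA match and is no independent control. With the classes matched on GC, the GATA difference went from 3.13 to 6.30 points (adjusted p = 5.9e-09, Fisher's exact test) and that of the composite site from 1.57 to 2.41 points, while shuffled controls 1 and 2 did not pass (1.02 and 1.00 points). The differences depended on the lists used, as did that of shuffled control 2, which ran from -5.81 to 9.45 points without a list. That of GATA turned to -5.55 points without G1E-ER4 list 1 and did not pass in the top 50% of the lists (1.15 points), in 400 bp windows (1.68) or without G1E list 1 (1.15), and it was 10.8 points without G1E list 2. That of the composite site turned to -1.95 or -1.59 points without either G1E-ER4 list and was 4.01 points without G1E list 2. It did not pass in 100 bp windows (0.179 points). In the top 50% (1.71 points) and without chromosomes 3, 7, 9 and 12 (1.25 points) it did not pass either, with fewer regions and a difference near the 1.57 points over all regions. The remaining 9 patterns, the 2 shuffled controls included, did not pass over all regions, among them KLF (26.3% and 27.2%), AP1 (5.23% and 6.20%) and the estrogen response element, found in 1 region of each class. Alternatives called KLF in both directions, at 13.4 points over whole regions, 5.25 in the top 50%, -4.30 matched on GC, -1.92 in 100 bp windows and -15.9 without G1E-ER4 list 2. Without the other lists it was at 2.62 (G1E-ER4 list 1), 2.60 (G1E list 1) and 3.09 points (G1E list 2). AP1 passed at -2.09 points in the top 50%, -0.808 in 100 bp windows and 4.98 over whole regions. It also passed at -1.26 points without chromosomes 3, 7, 9 and 12, and at -0.984 and -2.33 without G1E-ER4 list 1 or 2. Without G1E list 1 or 2 it was at -0.582 and 0.625 points. Shuffled controls 1 and 2 passed too, at -3.58 and -2.77 points in the top 50% and 9.61 and 10.6 over whole regions. Control 1 also passed without the 4 chromosomes (-2.62 points) and control 2 in 400 bp windows (-2.17). Calls in these settings are therefore not by themselves motif signals.

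**Figure D4:**
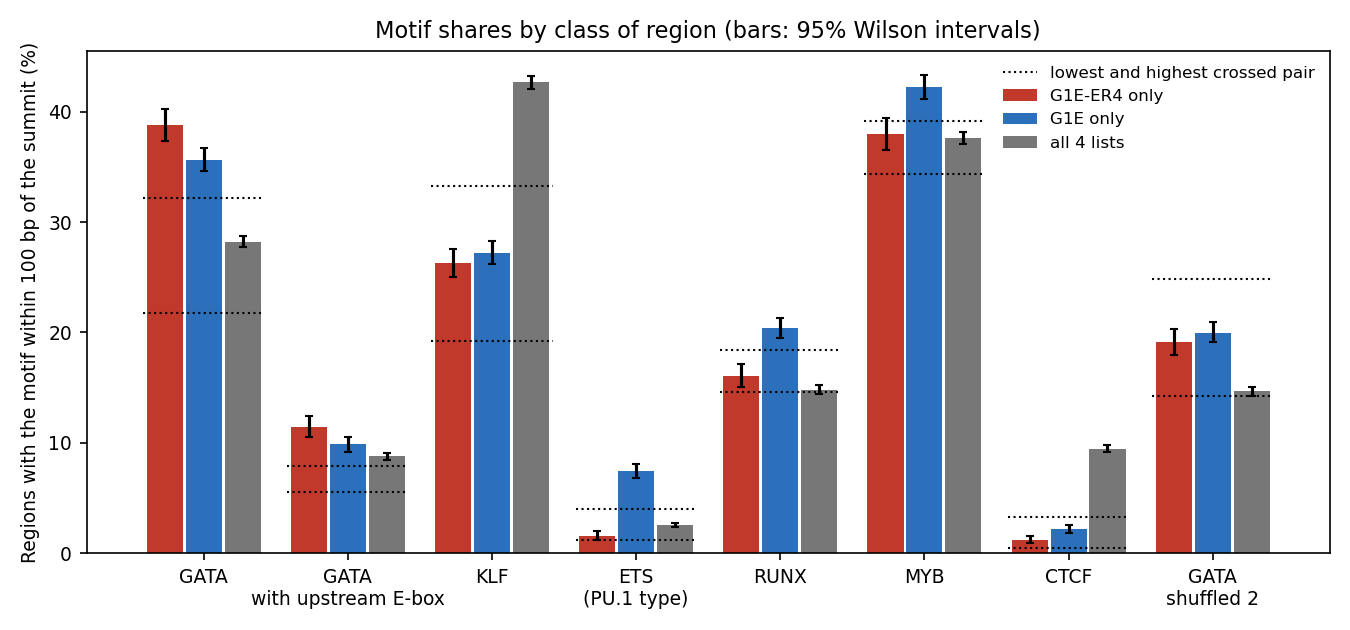
Share of regions with a motif within 100 bp of the summit (%, vertical axis) in G1E-ER4-only (red), G1E-only (blue) and all-4-list regions (grey), with Wilson 95% intervals and dotted lines at the lowest and highest crossed pair. The PU.1-type ETS motif is at 7.42% in G1E-only regions, above the dotted lines, and GATA is above them in both one-state classes.

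In the strong regions GATA, KLF and PU.1-type motifs differed in share between the 2 one-state classes. GATA was present in 77.8% of the 90 strong G1E-ER4-only regions (Wilson 95% interval 68.2 to 85.1%) and 53.9% of the 267 strong G1E-only regions (47.9 to 59.8%; adjusted p = 0.00044, Fisher's exact test). The composite GATA and E-box site was at 34.4% and 16.9% (adjusted p = 0.0034, Fisher's exact test), and the KLF motif, bound by Klf1, at 45.6% and 23.2% (adjusted p = 0.00044). The PU.1-type motif was at 1.11% and 14.98% (adjusted p = 0.00044, Fisher's exact test). RUNX, at 12.2% and 23.6%, did not pass (adjusted p = 0.0712, Fisher's exact test), and MYB (45.6% and 45.3%) and CTCF (1.11% and 0%) showed no lean to G1E. The crossed strong pairs, of 13 to 361 regions, had GATA at 27.7 to 46.2%, the composite site at 4.63 to 15.4%, KLF at 0 to 17.6% and the PU.1-type motif at 0 to 5.88%. These ranges are a weak noise level. The pairs of 17 and 13 regions had Wilson 95% intervals for GATA of 17.3 to 58.7% and 23.2 to 70.9%. Both contain the strong G1E-only share. In the larger pairs, 28.3% of 361 regions held bases of a primate repeat and 12.04% of 108 held primer bases. The change between the strong set and all regions was not tested for any motif. Strong G1E-ER4-only regions had a mean GC of 52.7% and strong G1E-only regions 48.6%. With these classes matched on GC, an alternative chosen after seeing the data like the next, the KLF difference went from 22.3 to 13.8 points among 87 regions per class and did not pass (adjusted p = 0.320, Fisher's exact test). The GATA difference went from 23.8 to 37.9 points, and the composite (19.5 points) and PU.1-type (-14.9 points) differences still passed. Without G1E-ER4 list 2 the differences of GATA (-3.66 points), the composite site (-4.34) and KLF (-21.7) had the opposite sign. GATA was also lower without G1E-ER4 list 1 (14.4) and did not pass without G1E list 1 (7.55), and the composite site was at 5.38 and 8.55 points without them. KLF was at 14.2 points without G1E list 1. The PU.1-type difference kept its sign and passed without each list, at -6.29 points without G1E-ER4 list 1 and -3.21 without G1E list 2.

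One-state regions also lay together along the genome. For G1E-ER4, 122 windows of 100 kb held 4 or more such regions, against a mean of 20.1 and at most 29 in 100 shuffles of the class among all regions. For G1E, 254 windows did so, against a mean of 117 and at most 147 (permutation p = 0.0099 for both, the smallest that 100 shuffles can give). The window richest in G1E-ER4-only regions lay in Nav2 (7:56600001-56700000, 13 regions), followed by windows at Sulf2 (2:165900001-166000000, 10) and Otog (7:53500001-53600000, 10). The richest G1E-only window held Tns4 and Igfbp4, an estrogen receptor target (11:98900001-99000000, 14 regions), and the next 4 were on chromosome 12. Shuffling within chromosomes, chosen after seeing the data, gave means of 43.2 and 179 windows. The crossed pairs were clustered as well, with 43 to 104 windows at 1.68 to 6.94 times their shuffled means, a range that contains the ratios of 6.07 for G1E-ER4 and 2.18 for G1E. Relative to the shuffled mean, the G1E-ER4 windows ran from 2.60 to 16.4 times and the G1E windows from 1.20 to 5.80 times over the alternatives.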

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

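Of the tests in this part, those on primer sequence, on repeat sequence near summits and on the position of peaks over Gata1 exons were chosen after the result was seen; the others were written before their result was seen, although the chromosome stretches had been picked from peak numbers already known.

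A signal appeared in strong regions of G1E list 1 alone, which enter the one-state classes only where G1E list 2 is left out. Their peaks also enter the similarity of the lists and the peak numbers per chromosome and window. In the mouse reference, 47.6% of these regions held 12 bases in a row that a primate repeat has and a related mouse repeat lacks. The share was 1.91% among regions in all 4 lists. Bases that the mouse repeat has and the primate repeat lacks were in 23.7% against 1.39%. The signal also reached the crossed pairs that set the noise level of strong regions. In the 361 regions of G1E-ER4 list 2 and G1E list 1, 28.3% held the primate repeat bases, and 14.96% held those of the mouse repeat. Human DNA in the library could not be told apart from a mouse repeat family, because matching places in the mouse genome lay under a peak of G1E list 1 at 1.73 times the share in G1E list 2, short of the ratio above 3 set in advance, and at 0.619 times for the mouse repeat. In the 108 regions of G1E-ER4 list 1 and G1E list 1, 12.04% (13 regions) held 10 bases in a row of a sequencing library primer, against 0.331% of regions in all 4 lists (p = 2.1e-16, Fisher's exact test) and at most 1.85% with 20 shuffled primers, but the reversed primer tried first as control was raised too (4.63% against 0.216%, p = 5.4e-06, Fisher's exact test), in 4 of its 5 regions without primer bases, so primer reads stay open as a cause.

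The strong one-state regions held the primer bases in 3.33% (G1E-ER4, 3 of 90 regions) and 0.375% (G1E). Against the 0.331% of regions in all 4 lists, the strong G1E-ER4-only share was raised too (p = 0.0036, Fisher's exact test). The primate repeat bases were in 1.11% and 0% of the strong one-state regions. No biological explanation was tested.

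The chromosome imbalance argues against GC content as its cause, because the odds ratio of chromosome 7 was 5.47 and that of chromosome 12 was 0.0755 with classes matched on GC. It also argues against a few dense groups as the whole cause, since an imbalance remained with 1 region per class and 100 kb window. The odds ratios then moved from 5.75 to 3.06 and from 0.0790 to 0.206, so part of its size lay in windows with several regions. A difference in DNA copy number between the lines is a candidate explanation. It predicts that regions in all 4 lists rank higher in G1E-ER4 on chromosome 7 up to 100 Mb and chromosome 9 from 110 Mb. On chromosome 12 from 30 Mb they should rank lower. In 12 of 12 medians, from 3 stretches and 4 pairs that share lists, they did so. With the 2 lists of each state averaged, the median shifts were 5.68 (95% interval 4.69 to 6.42), 5.29 (4.02 to 6.34) and -4.71 (-5.64 to -3.98) percentile points. The intervals come from resampling 1 Mb blocks and leave out the spread between lists. Single pairs on chromosome 7 ran from 3.08 to 6.85 points. The stretches were picked from peak numbers of the same lists, and any regional gain in signal predicts such shifts. The medians therefore do not single out copy number. The shifts were smaller at promoters (3.18, 2.98 and -2.82) than outside them (7.71, 6.93 and -7.37), a split whose cause was not tested, and an effect of Gata1 itself spread over these stretches stays open and was not tested.

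The exons of Gata1 under peaks of G1E-ER4 alone may hold reads of the restored gene's copy DNA, which has no introns, but the lists do not decide it. The first test tried asked how often all 4 summits of G1E-ER4 list 1 would fall in exons by chance, and gave 0.0621. The tests added after it moved the peaks of a list around the stretch of 5 exons. Peaks of list 1 covered 78.3% of exon bases and 29.5% of intron bases, and 0.0319 of all shifts covered as much exon, while those of list 2 covered 81.3% and 59.2%, and 0.194 of all shifts did so. Opening of a regulatory site in the exons cannot be told apart by motif, since 1 of the 2 regions had a GATA motif near its summit, against 28.2% of exon regions in all 4 lists.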

How the results depend on the processing

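The alternatives without chromosomes 3, 7, 9 and 12, without regions with primer or repeat bases, on motifs in strong regions, with random gene lists matched also on chromosome, and with shuffles within chromosomes were chosen after seeing the data; all others were fixed before. Of the alternative values, 141 kept direction and side of the threshold, or size for a count, 34 moved, 11 lost and 10 gained a call, and 19 turned direction. Leaving out a list lets the single list left decide for its state, which by itself enlarges the classes. Without G1E list 2 the classes take in all regions of G1E list 1 alone, 449 of whose 944 strong regions held primate repeat bases. G1E-ER4-only regions numbered 2229 in the top 50%, 1019 in the top 20000, 744 with the asymmetric threshold and 7003 to 38007 without a list. G1E-only regions numbered 4099, 1232, 1982 and 12067 to 33376. Regions in all 4 lists numbered 11569 with 50% reciprocal overlap, 18829 with summits within 100 bp and 11289 in the top 20000. The first 2 of these counts are peaks of G1E-ER4 list 1 and not merged regions. Strong regions numbered 1 (G1E-ER4) and 3 (G1E) in the top 10%, and 219 to 1210 and 790 to 1438 without a list. Fewer peaks qualify in the settings with a rank limit by construction, while all peaks enter those with 50% reciprocal overlap or summits within 100 bp. Gene lists past the test numbered 1 with matching on chromosome and 0 to 3 without a list. Motifs past the test numbered 14 over whole regions and 8 to 14 without a list. Directions turned for GATA without G1E-ER4 list 1 (-5.55 points; range without a list -5.55 to 10.8), for GATA with E-box without G1E-ER4 list 1 (-1.95) or list 2 (-1.59; range -1.95 to 4.01), for RUNX (10.8) and MYB (7.82) over whole regions, and without G1E list 2 for MYB (1.76; range -4.15 to 1.76) and CTCF (2.06; range -3.13 to 2.06). KLF, not past the test over all regions, turned from -0.942 to 0.909 in 400 bp windows, 13.4 over whole regions, 5.25 in the top 50%, 0.259 without the 4 chromosomes, and without 3 of the lists (range -15.9 to 3.09). AP1 turned to 4.98 over whole regions and 0.625 without G1E list 2 (range -2.33 to 0.625). In strong regions directions turned without G1E-ER4 list 2 for GATA (-3.66; range -3.66 to 28.7), GATA with E-box (-4.34; range -4.34 to 16.7) and KLF (-21.7; range -21.7 to 19.1). For these turns and for the gene list and motif counts the cause was not tested. The PU.1-type difference kept its sign and call in all 11 alternatives, and chromosome 7 and 12 odds ratios, the list similarity, the promoter difference and clustering kept direction and call, where tested, in all alternatives run for them. Their sizes moved, with odds ratios of 2.24 for chromosome 7 and 0.370 for chromosome 12 and a similarity difference of 0.229 points under 50% reciprocal overlap. The PU.1-type difference shrank to -1.39 points without G1E list 2, where the G1E-only share was 3.18%. Ranking by the deposited p-value was not run, because that column holds no values. No paired analysis was possible because each state has 1 sample and its list numbers name no shared culture or day. Read depth is unknown, so a missing peak may lie just under the threshold: judged within the top 50% of all lists 2229 G1E-ER4-only regions were counted, and 744 when absence was judged over whole lists.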

Other observations

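The genes in this part were chosen after their values were seen, and none of its values was tested apart from 1 pair of shares.

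Strong G1E-only regions lay at further genes of the progenitor and erythroid lists beyond the distance used for gene lists or below the rank needed to be named. One lay 10882 bp from a start of Il1rl1, the receptor of interleukin 33 (1:40474711-40475931, percentiles 84.5 and 88.9 in G1E). Others lay 145275 bp from Cdk6, a cell cycle kinase of progenitors (5:3197971-3199565, 82.8 and 90.7), 321648 bp from Runx1 (16:93147042-93148727, 84.3 and 92.6) and 178226 bp from Ikzf2 (1:69553650-69554941, 79.8 and 88.3). Jak2, the kinase of the erythropoietin receptor, had one 1638 bp from a start (19:29324243-29325011, 76.0 and 88.8) and another 62756 bp away. An intron of Sox6, a regulator of globin switching, held one (7:122692724-122694438, 75.8 and 88.0), and another lay 9227 bp from Klf3 (5:65185168-65185636, 82.4 and 76.2). In all, 11 of 267 strong G1E-only regions (4.12%) had a gene of the 14 lists as their nearest gene, and 2 of 90 strong G1E-ER4-only regions (2.22%), both at Gata1 (p = 0.530, Fisher's exact test), so the shares did not differ by this test.

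At Esr1, the estrogen receptor gene, G1E-ER4 list 2 held 6 peaks, 3 of them with summits in exons, among these 10:5345120-5345594 (percentile 60.1) and 10:5406867-5407417 (49.0) near the 3' end of the gene. G1E-ER4 list 1 had 1 of 5 summits in an exon, and each G1E list 0 of 5. Both G1E lists shared an intron region (10:5558821-5559851, percentiles 77.6 and 90.6) that the G1E-ER4 lists lacked.

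Positions within the lists were most alike in the G1E pair, where Spearman's rho across the regions of both was 0.818 over 49240 regions, and it was 0.717 in the G1E-ER4 pair. Across states it was 0.773 and 0.764 for G1E-ER4 list 2 with G1E lists 1 and 2, and 0.695 and 0.694 for G1E-ER4 list 1. Regions are not independent replicates.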
